A study of Mus musculus with 4 samples.

How the data were processed

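RNA of mouse DC2.4 cells was sequenced after 24 h with vehicle (2 libraries) or with ginsenoside Rb1 at 10 uM (2 libraries). Per the labels' protocols, libraries were made from total RNA and read in pairs on an Illumina instrument. The extraction reagent, library kit, read length, strand use, aligner, counting program and annotation release are not given in the sources used here. The submitters' processing notes name the builds GRCm39 and mm39. The gene coordinates in the deposited table are nevertheless those of GRCm38: 54495 of its 54532 gene IDs are in GENCODE M21, and 98.3% of these have identical chromosome, start and end there. All coordinates given are the table's own and are named GRCm38.

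The authors deposited raw counts per gene, which are whole numbers with different totals in each library, and replicates were not pooled. The authors also deposited FPKM values for the same genes. Each FPKM value equals the count divided by the gene length in kb and by a constant per library. That constant is not the plain total: it was 0.908 and 0.943 times the count total in vehicle replicates 1 and 2, and 1.09 times in both Rb1 replicates, so the deposited FPKM hold a composition scaling. In 27 rows the gene symbol had been turned into a date and was restored from the gene ID. Gene names are those of the table, and list members were matched through older symbols, except H2bc24, for which no row was matched.

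Groups were taken from the labels' treatment entry and library names from the column names. Replicates of a group were compared before averaging. Over genes with at least 20 counts in the pair, the chi-square per degree of freedom was 11.8 between the vehicle replicates and 2.87 between the Rb1 replicates, and the median absolute log2 ratio was 0.172 and 0.0830, so neither pair agreed within sampling noise. The labels call them biological replicates and do not say how the cultures were separated, so p-values measure the spread between these samples. The labels' batch entry holds the replicate number in both groups, and the numbers were therefore taken to pair the samples. The deviations of the same-numbered libraries from their group means correlated at -0.05 across genes.

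Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr, robust dispersion, group as the only term, 2 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over 13518 genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are TMM-normalised, and a group's mean and SD are over its 2 libraries. Total counts lay between 17829784 and 18641021. A count of 0 allows up to 3 counts per library, which is between 0.15 and 0.18 CPM, and folds against a group at 0 are set against that floor. For groups with 1 to 3 counts in all, the ratio has an exact (Clopper-Pearson) 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

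For 39 lists written before the data were examined, camera of limma 3.58.1 was run with a preset correlation of 0.01 on log2 CPM (prior count 2), with an estimated correlation and with fry beside it, over the 35 lists with at least 5 tested members. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom, which leaves little power. With the preset, its p rests on the assumed 0.01. Named genes followed a rule written beforehand. It took the 10 largest changes and the 5 smallest p in each direction, among called genes whose groups do not overlap and whose higher mean is at least 1 CPM, without unnamed gene models and pseudogenes. It also took up to 4 called members of each list with the smallest p, or where a list has none its 2 most highly expressed members, and fixed readout genes: Cd80, Cd86, Cd40, H2-K1, H2-Ab1, Cd274, Ccr7, Il6, Tnf, Il1b, Il12b, Il10 and Myc. Some of these genes are left out of the text for length, and some are not reported here.

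The procedure was tested on simulated counts with the means and sizes of these libraries over 13518 genes. Dispersions came from the fitted trend, and no length trend or composition shift was put in. Of 100 genes changed by 1.5 times it called 61, of 100 changed by 2 times it called 74, and of 13318 unchanged genes it called 11, with 0 in the wrong direction among the changed genes called. In the data 72% of the genes tested were called and a length trend was present, so these rates need not hold there. Alternatives were relative log expression factors, library totals, no count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) with a mean FPKM of at least 0.5, on log2(FPKM + 0.1) and without that filter, the replicate number as a block, each library left out in turn, an added limit of 1 on the absolute log2 fold change, and protein-coding genes only. After seeing the data, a loess correction (span 0.4) of each library for gene length and GC content was added, without and with the block. GC content came from the GENCODE M21 transcripts and was known for 99.9% of the genes tested. The work was done in R 4.3.3 and Python 3.11.15.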

Results

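The transcriptome of DC2.4 cells was measured by paired-end RNA sequencing after 24 h with vehicle or with ginsenoside Rb1 at 10 uM. DC2.4 is an immortalised mouse dendritic cell line. Ginsenoside Rb1 is a triterpene saponin of ginseng, and the name Rb1 is used here for the compound, not for the retinoblastoma gene. Each group had 2 libraries, which the labels call biological replicates. The libraries held 18641021 and 17908591 counts with vehicle and 18378029 and 17829784 counts with Rb1, and between 18762 and 19015 genes had at least 1 count. Of the 54532 genes listed, 13518 had enough counts to be tested. Levels below are CPM (counts scaled to library size) after TMM normalization, as mean ± SD with n = 2 per group, and adjusted p-values are from edgeR's quasi-likelihood test unless the set test (camera) is named.

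The comparison of Rb1 with vehicle asked which transcripts differ in cells treated with the compound. Transcripts of inflammatory mediators, chemokines, interferon-stimulated genes, hypoxia targets and glycolytic enzymes were lower with Rb1, while those of mitosis, cholesterol and fatty acid synthesis and the mitochondrial genome were higher. As sets these passed with a preset correlation between genes, and none passed when that correlation was estimated from the libraries (smallest adjusted p 0.169). The estimated form rests on 2 residual degrees of freedom and has little power here. The chemokine gene Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, GRCm38) fell from 919 ± 10.1 to 1.83 ± 0.0305 CPM, a 503-fold lower level. The mitotic kinesin gene Kif11 (ENSMUSG00000012443, chromosome 19, 37376403 to 37421859) rose from 28.8 ± 0.463 to 179.6 ± 5.42 CPM, a 6.24-fold higher level. At an adjusted p under 0.05, 4822 genes were higher and 4909 lower, together 72% of the genes tested. Changes of at least 2-fold numbered 1921 higher and 2196 lower, and changes of at least 4-fold numbered 375 higher and 910 lower. In 86.3% of the genes tested both Rb1 libraries lay on the same side of both vehicle libraries, where chance gives 33.3% on average. Genes measured in the same 4 libraries move together, so this share does not count independent results. The labels' batch entry holds the replicate number, and the log2 fold changes within replicate 1 and within replicate 2 correlated at 0.924 across genes, which are not independent replicates. All called genes (100%) lay on the same side in both. This gives no separate support, since of the 9731 called genes 9730 had groups that do not overlap, which fixes the side.

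Scaling by library totals in place of TMM called 6128 genes higher and 3662 lower, so that 62.6% of calls were higher against 49.6%. It moved the median log2 fold change of all genes from -0.01 to 0.23, and the directions below are relative to the TMM scale. Long gene models were also higher with Rb1: models over 5 kb held 29.1% ± 1.72 of the counts with vehicle and 40.3% ± 0.302 with Rb1, and models under 1 kb held 6.84% ± 0.529 and 4.58% ± 0.0734. With the length and GC trend of each library removed, an alternative chosen after seeing the data, 7703 of the 9731 calls remained, 1736 were lost and 292 reversed.

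**Figure D1:**
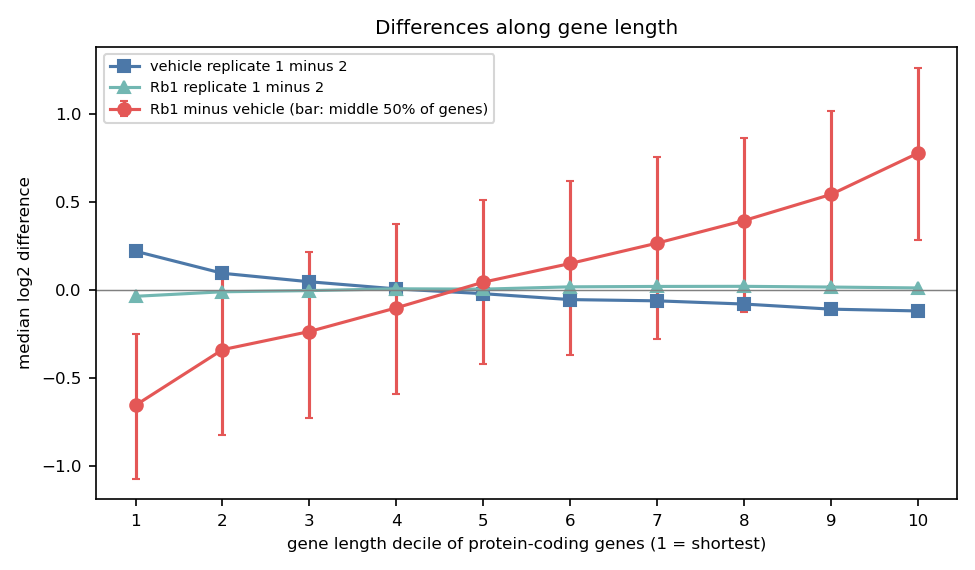
Median log2 difference of protein-coding genes of at least 5 CPM in 10 classes of gene length, for Rb1 minus vehicle (red, bars over the middle 50% of genes), vehicle replicate 1 minus 2 (blue) and Rb1 replicate 1 minus 2 (green). The median of Rb1 minus vehicle runs from -0.66 in the shortest class to 0.77 in the longest, and that of vehicle replicate 1 minus 2 from 0.22 to -0.12.

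**Figure D2:**
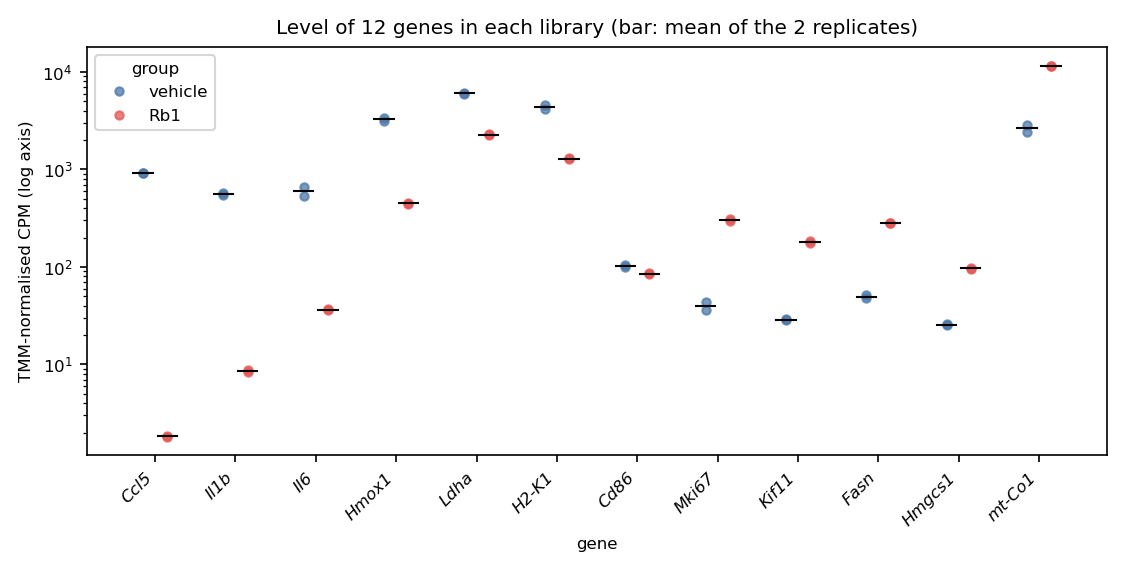
TMM-normalised CPM of 12 genes in each of the 4 libraries on a log axis, with vehicle in blue, Rb1 in red and a black bar at the mean of the 2 replicates. Ccl5 lies at 919 with vehicle and 1.83 with Rb1, Cd86 at 102 and 85, and Kif11 at 28.8 and 179.6.

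Of 39 gene lists fixed before the data were examined, 35 had at least 5 tested members. The set test called 5 of them higher and 18 lower. None was called when the correlation between genes was estimated from the 4 libraries, where the smallest adjusted p was 0.169. Little could pass that form, with its 2 residual degrees of freedom. Interferon-stimulated genes, with 36 of 36 lower, had an unadjusted camera p of 0.0127 there. A failure in that form, given beside each list below, therefore does not show that a list did not move. Adjusted over the list alone, the counts of changed members were equal to those over all genes tested in 37 of the 39 lists. The exceptions were G1/S and DNA replication, with 4 members lower in place of 2, and MHC class I presentation, with 16 in place of 15.

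**Figure D3:**
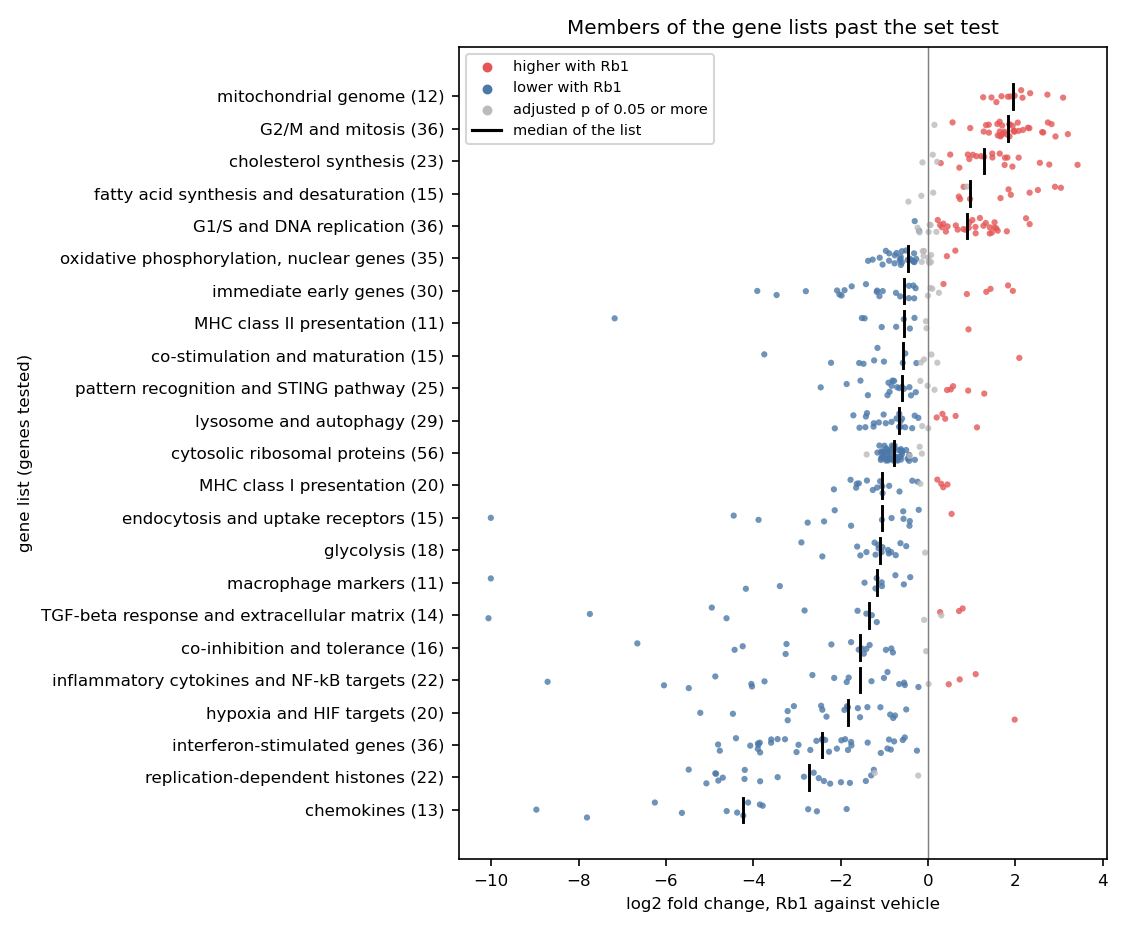
Log2 fold change, Rb1 against vehicle, of each tested member of the 23 lists past the set test, with the number tested in brackets and a black line at the list median. Red and blue points are members higher and lower at an adjusted p under 0.05, grey points did not pass. Medians run from -4.23 for chemokines to 1.94 for the mitochondrial genome.

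All 13 tested chemokine genes were lower with Rb1, with a median log2 fold change of -4.23 (camera adjusted p = 2.7e-07, and adjusted p = 0.321 with an estimated correlation). Besides Ccl5, Cxcl3 fell from 557 ± 40.9 to 7.29 ± 0.344 CPM (76.5-fold lower), the neutrophil-attracting chemokine gene Cxcl2 fell from 1773 ± 158 to 94.5 ± 0.77 CPM, and the interferon-inducible Cxcl10 fell from 136 ± 10.1 to 7.85 ± 0.213 CPM. Of 22 inflammatory cytokines and NF-kB targets, 18 were lower, 3 higher and 1 did not pass (camera adjusted p = 1.2e-04, and adjusted p = 0.169 with an estimated correlation). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), which encodes interleukin-1 beta, fell from 566 ± 19.7 to 8.55 ± 0.274 CPM (66.1-fold lower). Il1a fell from 173 ± 11.5 to 0.405 ± 0.0626 CPM (426-fold), Csf3, the granulocyte colony-stimulating factor gene, from 811 ± 31.8 to 18.2 ± 1.28 CPM (44.6-fold), and Il6 from 602 ± 92.3 to 36.5 ± 0.644 CPM (16.5-fold). Tnf fell less, from 163 ± 19 to 46.2 ± 2.41 CPM (log2 fold change -1.82, SE 0.09, adjusted p = 1.8e-08). Hcar2, the receptor of niacin and beta-hydroxybutyrate, was among the genes with the smallest p and fell from 249 ± 1.31 to 4.77 ± 0.18 CPM.

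Every one of the 36 interferon-stimulated genes tested was lower with Rb1 (median -2.42, camera adjusted p = 1.3e-12, and adjusted p = 0.169 with an estimated correlation). With library totals 35 of them were called lower. Ifit3 fell from 222 ± 9.21 to 10.5 ± 0.0853 CPM, Rsad2, which encodes viperin, from 714 ± 38.9 to 49.7 ± 0.763 CPM, the nucleic acid sensor gene Zbp1 from 175 ± 14.8 to 6.25 ± 0.285 CPM and Gbp3 from 146 ± 2.52 to 8.68 ± 0.235 CPM. Among 25 genes of pattern recognition and the STING pathway, 17 were lower, 5 higher and 3 not called (camera adjusted p = 0.0214, and adjusted p = 0.487 with an estimated correlation), while 14 were lower and 6 higher with library totals (median -0.35 against -0.60) and the median was -0.36 with the length and GC trend removed. The lipopolysaccharide co-receptor gene Cd14 fell from 301 ± 30.5 to 116 ± 0.252 CPM, Tlr6 from 29 ± 0.125 to 9.92 ± 0.386 CPM and Tlr2 from 439 ± 17.5 to 246 ± 0.932 CPM. Ddx58, an older symbol of the RIG-I gene, fell from 245 ± 2.8 to 143 ± 1.76 CPM. Among 30 immediate early genes 20 were lower and 6 higher (camera adjusted p = 0.0111, and adjusted p = 0.288 with an estimated correlation), and those with the smallest p were Dusp1, from 205 ± 14 to 18.6 ± 0.886 CPM, Ier3, from 1214 ± 135 to 80.8 ± 5.13 CPM, and Jun, from 196 ± 3.9 to 46.4 ± 0.939 CPM. In that list 13 were lower and 7 higher with library totals (median -0.29 against -0.54). With the length and GC trend removed 14 were lower and 6 higher, and it did not pass (median -0.33, adjusted p = 0.0893, over its alternatives 0.00316 to 0.288).

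Genes of antigen presentation through MHC class I were mostly lower: of 20 tested, 15 fell, 4 rose and 1 did not pass (camera adjusted p = 0.00191, and adjusted p = 0.288 with an estimated correlation). With library totals 13 class I genes were lower and 4 higher (median -0.80 against -1.04), and with the length and GC trend removed 13 were lower and 1 higher. H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000333) fell from 4401 ± 316 to 1287 ± 13.4 CPM, H2-D1 from 3614 ± 207 to 1167 ± 34.6 CPM and H2-T23 from 528 ± 55 to 118 ± 3.54 CPM. Class I genes share sequence, and reads could have been split between them, so their single values are uncertain. The proteasome activator gene Psme2 fell from 364 ± 27.4 to 138 ± 0.534 CPM. Of 11 class II genes, 8 were lower, 1 higher and 2 not called (camera adjusted p = 0.0265, and adjusted p = 0.495 with an estimated correlation), with Cd74, the invariant chain, from 1055 ± 2.32 to 506 ± 15.9 CPM, and cathepsin S, Ctss, from 818 ± 75.7 to 299 ± 9.13 CPM. In the class II list 6 were lower and 1 higher with library totals (median -0.31 against -0.55). Removing the length and GC trend turned the median of this list from -0.55 to 0.03 and ended its call (adjusted p = 0.582), as did leaving out Rb1 replicate 1 (adjusted p = 0.0783, over all alternatives 0.0209 to 0.626). H2-Ab1 had 7 and 15 counts with vehicle and 4 and 5 with Rb1, too few to be tested.

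Among 15 co-stimulation and maturation genes 10 were lower, 1 higher and 4 not called (camera adjusted p = 0.0111, and adjusted p = 0.288 with an estimated correlation), while 8 were lower and 3 higher with library totals (median -0.33 against -0.58). Tnfrsf9, encoding 4-1BB, fell from 3277 ± 76.6 to 244 ± 6.11 CPM (13.4-fold), Il15 from 34.6 ± 4.58 to 7.43 ± 0.73 CPM, Cd40 from 75.8 ± 8.02 to 25.4 ± 0.718 CPM and Cd80 from 78.1 ± 1.87 to 33.2 ± 0.399 CPM. Cd86 (ENSMUSG00000022901, chromosome 16, 36603869 to 36666081), the other ligand of CD28, differed little, at 102 ± 2.56 CPM with vehicle and 85 ± 1.52 with Rb1 (log2 fold change -0.27, SE 0.07, adjusted p = 0.00733). Its call was lost with library totals (log2 fold change -0.02, adjusted p = 0.859) and without Rb1 replicate 1 or Rb1 replicate 2 (adjusted p = 0.138 and 0.0847), and over all alternatives without a fold limit its adjusted p lay between 7.0e-06 and 0.859. The maturation marker Ccr7 had 8 and 12 counts with vehicle and 3 and 2 with Rb1, and Il12b had 6 and 5 with vehicle and 0 in both Rb1 libraries. Neither was tested. Genes of co-inhibition and tolerance were lower too, 15 of 16 with 0 higher (camera adjusted p = 4.5e-06, and adjusted p = 0.169 with an estimated correlation). Arginase 1, Arg1, fell from 77.5 ± 6.55 to 0.761 ± 0.0546 CPM (102-fold), Il10 from 9.25 ± 0.632 to 0.479 ± 0.312 CPM, Tnfaip3, which encodes the NF-kB inhibitor A20, from 121 ± 12.3 to 26.1 ± 0.237 CPM, Socs3 from 228 ± 14 to 75.8 ± 6.38 CPM, Pvr from 370.0 ± 10.6 to 134 ± 3.45 CPM and Cd274, encoding PD-L1, from 144 ± 14.2 to 73.9 ± 0.089 CPM.

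Of 20 hypoxia and HIF targets, 19 were lower and 1 higher (median -1.84, camera adjusted p = 4.6e-07, and adjusted p = 0.169 with an estimated correlation). The vasodilator peptide gene Adm fell from 405 ± 39.1 to 10.9 ± 0.365 CPM (37.1-fold), the lipid droplet gene Hilpda from 894 ± 106 to 40.4 ± 4.72 CPM, Ndrg1 from 1363 ± 84.4 to 147 ± 5.19 CPM and the collagen prolyl hydroxylase gene P4ha2 from 380.1 ± 0.42 to 45.2 ± 3.25 CPM. Glycolysis genes fell in 17 of 18 cases, with 1 not called (camera adjusted p = 3.4e-06, and adjusted p = 0.169 with an estimated correlation). The glucose transporter gene Slc2a1 fell from 2456 ± 53 to 459 ± 1.22 CPM, the lactate transporter gene Slc16a3 from 859 ± 22.4 to 279 ± 4.47 CPM, Tpi1 from 3340.3 ± 254 to 1142 ± 6.43 CPM and Ldha, lactate dehydrogenase A, from 6038 ± 129 to 2274 ± 55.2 CPM. Slc2a1 and Pdk1 stand in both lists. Other lists share members too, among them Anln in the hypoxia and mitosis lists and Mrc1 in the uptake receptor and macrophage marker lists.

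Mitosis genes rose: 35 of 36 were higher and 1 was not called (median 1.84, camera adjusted p = 1.7e-12, and adjusted p = 0.169 with an estimated correlation). The proliferation marker Mki67 rose from 39.8 ± 5.22 to 302 ± 11.5 CPM (7.57-fold), topoisomerase Top2a from 95.6 ± 10.3 to 586 ± 12.4 CPM and the kinetochore motor gene Cenpe from 9.4 ± 1.01 to 66.9 ± 2.69 CPM. The condensin gene Ncapd2, from 31.4 ± 1.42 to 196 ± 7.81 CPM, and the kinesin gene Kif15, from 14.9 ± 0.615 to 112 ± 3.46 CPM, were among the rises with the smallest p, as was Arhgap32, from 5.64 ± 0.608 to 66.5 ± 0.927 CPM. Of 36 genes of G1/S and DNA replication 28 were higher, 2 lower and 6 not called (camera adjusted p = 1.2e-05, and adjusted p = 0.169 with an estimated correlation). With library totals 0 were called lower. Examples are the replicative helicase gene Mcm6, from 109 ± 1.2 to 314 ± 5.23 CPM, Rrm1, from 127 ± 8.21 to 375 ± 8.24 CPM, and the DNA polymerase gene Pole, from 13 ± 2.26 to 61.6 ± 1.66 CPM. Replication-dependent histone genes went the other way, 20 of 22 lower and 2 not called (median -2.73, camera adjusted p = 7.5e-07, and adjusted p = 0.288 with an estimated correlation). Hist1h1c fell from 1060.4 ± 132 to 173 ± 2.9 CPM and Hist1h2bc from 402 ± 76.5 to 71 ± 0.623 CPM. These are short, multi-copy genes whose usual mRNAs lack a poly(A) tail, and how the libraries captured RNA is not given in the sources used here. The cell-cycle inhibitor gene Cdkn1a fell from 1398 ± 8.82 to 523 ± 4.63 CPM, and Myc fell from 14.1 ± 1.08 to 0.964 ± 0.050 CPM.

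Genes of cholesterol synthesis rose together, 20 of 23 with 3 not called (median 1.29, camera adjusted p = 1.2e-06, and adjusted p = 0.169 with an estimated correlation). Idi1 rose from 7.97 ± 0.921 to 47.1 ± 1.17 CPM (5.91-fold), Hmgcs1, a mevalonate pathway enzyme, from 25.4 ± 0.394 to 97.2 ± 1.94 CPM, and Srebf2, which encodes the transcription factor SREBP2, from 67.1 ± 5.69 to 237 ± 9.16 CPM. In fatty acid synthesis and desaturation 11 of 15 were higher and 4 not called (camera adjusted p = 5.7e-04, and adjusted p = 0.415 with an estimated correlation). Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), fatty acid synthase, rose from 49.4 ± 2.69 to 283 ± 1.54 CPM, acetyl-CoA carboxylase Acaca from 15.2 ± 3.86 to 114 ± 1.12 CPM and Elovl6 from 14.2 ± 0.738 to 71.3 ± 0.436 CPM. Of 13 genes of LXR and cholesterol efflux 7 were lower and 2 higher, without passing the set test (camera adjusted p = 0.0938), while 6 were lower and 4 higher with library totals (median -0.36 against -0.60). The lipid droplet coat gene Plin2 fell from 4552 ± 93.7 to 576 ± 11.5 CPM, and Scd2 rose from 328 ± 25 to 640.1 ± 3.53 CPM. Of 16 genes of fatty acid oxidation 9 were lower and 1 higher (camera adjusted p = 0.0795), with Angptl4 from 64.2 ± 6.61 to 7.12 ± 1.45 CPM. That list passed as lower with the length and GC trend removed (adjusted p = 0.0447), though not with the replicate block as well (adjusted p = 0.0553), and without vehicle replicate 1 (adjusted p = 0.0481, over its alternatives 0.00188 to 0.341), while with library totals 6 members were lower and 5 higher.

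All 12 tested mRNAs of the mitochondrial genome were higher (median 1.94, camera adjusted p = 1.3e-05, and adjusted p = 0.321 with an estimated correlation). The cytochrome oxidase subunit gene mt-Co1 (ENSMUSG00000064351, chromosome MT, 5328 to 6872) rose from 2635 ± 312 to 11568 ± 80 CPM, mt-Nd4 from 95.4 ± 5.19 to 428 ± 1.15 CPM and mt-Nd1 from 249.8 ± 21.1 to 924 ± 15.9 CPM. The mitochondrial rRNA mt-Rnr1 fell from 1338 ± 284 to 548 ± 5.56 CPM, and mt-Rnr2 stood at 466 ± 125 and 513 ± 11.5 CPM (adjusted p = 0.44); both were chosen after their values were seen. Nuclear genes of oxidative phosphorylation were lower in 24 of 35 cases, higher in 2 and not called in 9 (median -0.46, camera adjusted p = 0.00317, and adjusted p = 0.514 with an estimated correlation). In that list 17 were lower and 7 higher with library totals (median -0.22 against -0.46). Ndufa1 fell from 112 ± 13.7 to 43.3 ± 1.37 CPM and Ndufs3 from 148 ± 25 to 68.8 ± 0.942 CPM. Cytosolic ribosomal protein genes were lower in 52 of 56 cases with 4 not called (median -0.79, camera adjusted p = 4.6e-08, and adjusted p = 0.495 with an estimated correlation), for example Rps3 from 2805 ± 229 to 1444 ± 3.84 CPM and Rpl19 from 1793 ± 257 to 848 ± 15.4 CPM. Both lists hold short gene models. With the length and GC trend removed, the median of the ribosomal proteins was -0.41, with 40 called lower, and that of the nuclear oxidative phosphorylation genes was -0.14, with 16 lower and 8 higher, where the list no longer passed (adjusted p = 0.366, over its alternatives 2.5e-04 to 0.514).

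Endocytosis and uptake receptors were lower in 14 of 15 cases and higher in 1 (camera adjusted p = 1.9e-04, and adjusted p = 0.169 with an estimated correlation). With library totals 11 uptake receptors were lower and 1 higher (median -0.81 against -1.05), and with the length and GC trend removed 14 were lower and 0 higher. The Fc receptor genes Fcgr4 and Fcgr3 fell from 35.7 ± 2.56 to 1.63 ± 0.252 CPM and from 61.8 ± 2.72 to 4.2 ± 1.35 CPM. The mannose receptor gene Mrc1 fell from 7.07 ± 1.25 CPM to 0 counts in both Rb1 libraries, at least 46.4-fold lower at a floor of 3 counts per library. Lysosome and autophagy genes were lower in 22 and higher in 5 of 29 cases (camera adjusted p = 4.4e-04, and adjusted p = 0.169 with an estimated correlation; 19 were lower and 6 higher with library totals (median -0.41 against -0.66)), with Npc2 from 1183 ± 107 to 269.7 ± 3.54 CPM, cathepsin D, Ctsd, from 1137 ± 27.4 to 383 ± 14.5 CPM, and Sqstm1, encoding p62, from 1982 ± 6.86 to 733 ± 12.4 CPM. In the TGF-beta and extracellular matrix list 9 of 14 were lower, 3 higher and 2 not called (camera adjusted p = 0.0387, and adjusted p = 0.415 with an estimated correlation). The macrophage elastase gene Mmp12 fell from 659.8 ± 44.5 to 0.604 ± 0.417 CPM (1083-fold lower). The Rb1 libraries held 18 and 6 Mmp12 counts, so that ratio is rough. The collagenase gene Mmp13 fell from 34.1 ± 0.869 to 0.153 ± 0.0752 CPM. This list did not pass without vehicle replicate 1 (adjusted p = 0.0516) or without vehicle replicate 2 (adjusted p = 0.0939, over its alternatives 0.00193 to 0.415).

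Dendritic cell lineage genes were split, 9 of 14 lower and 4 higher (camera adjusted p = 0.169), and 8 were lower and 5 higher with library totals (median -0.48 against -0.73). Id2 fell from 94.6 ± 16.2 to 8.0 ± 1.0e-03 CPM, the integrin gene Itgax, encoding CD11c, from 28.9 ± 1.9 to 3.32 ± 0.32 CPM, and Bcl6 rose from 21.4 ± 1.47 to 63.7 ± 2.05 CPM. Markers of other cell types moved with the groups as well. All 11 tested macrophage markers were lower (camera adjusted p = 1.9e-04, and adjusted p = 0.169 with an estimated correlation), among them Gpnmb, from 1159 ± 47.2 to 513 ± 5.04 CPM, lysozyme, Lyz2, from 282 ± 20 to 103 ± 4.88 CPM, and Maf, from 25.2 ± 2.9 to 1.39 ± 0.292 CPM. With library totals 10 were called. The 3 neutrophil and mast cell markers tested had 0 counts in both Rb1 libraries and low levels with vehicle: S100a8 2.03 ± 0.515 CPM (at least 13.3-fold lower), Camp 1.79 ± 0.514 (at least 11.8-fold) and Gata2 0.716 ± 0.172 (at least 4.7-fold). Their median log2 fold change was -8.03 as fitted and -3.56 at those bounds. All 4 fibroblast, epithelial or endothelial markers tested were lower, among them Dcn, from 6.71 ± 0.072 to 0.353 ± 0.207 CPM, and Acta2, from 1.61 ± 0.682 to 0.737 ± 0.124 CPM, whose call was lost under 9 of 17 alternatives without a fold limit (adjusted p 0.00276 to 0.317). Without vehicle replicate 1 its log2 fold change was -0.62 against -1.12. Both lymphocyte markers tested were lower, Lck from 21.7 ± 0.621 to 9.75 ± 0.139 CPM and Pax5 from 5.97 ± 0.311 to 1.12 ± 0.0466 CPM.

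Stress lists did not pass the set test, although single members moved far. In the NRF2 list 7 genes were higher and 8 lower of 23 (camera adjusted p = 0.788), with heme oxygenase 1, Hmox1, from 3259 ± 149.6 to 449 ± 5.7 CPM (7.26-fold lower). Its median was -0.07 and turned to 0.18 with library totals. Metallothionein Mt1 fell from 2702 ± 133 to 193 ± 11.1 CPM, in a list of 5 with 3 lower and 1 higher (adjusted p = 0.246; 2 were lower and 1 higher with library totals (median -0.16 against -0.41)), while the zinc importer gene Slc39a10 rose from 5.55 ± 0.735 to 27.9 ± 0.308 CPM. The integrated stress response had 12 higher and 15 lower of 30 (adjusted p = 0.458), with Atf3 from 292 ± 15.2 to 77.8 ± 1.62 CPM, and the balance turned with library totals, to 13 higher and 11 lower (median -0.07 against -0.31). The unfolded protein response had 7 higher and 7 lower of 23 (adjusted p = 0.867), and its median of -0.07 turned to 0.18 with library totals. The heat shock list had 9 higher and 4 lower of 16 (adjusted p = 0.203), with the mitochondrial chaperonin gene Hspd1 from 509 ± 0.402 to 1096 ± 26.6 CPM. With library totals 12 heat shock genes were higher and 3 lower (median 0.46 against 0.21), and with the length and GC trend removed 9 were higher and 7 lower. The p53 list had 11 higher and 8 lower of 24 (adjusted p = 0.354), with Zmat3 from 17 ± 1.51 to 84.7 ± 2.77 CPM. With library totals 14 p53 targets were higher and 4 lower (median 0.35 against 0.11).

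The MYC and ribosome biogenesis list had 17 higher and 6 lower of 32 (camera adjusted p = 0.098), with Cad, which starts pyrimidine synthesis, from 133 ± 15.4 to 478 ± 3.06 CPM. In that list 23 were higher and 2 lower with library totals (median 0.53 against 0.28). The list passed as higher with the length and GC trend removed (adjusted p = 0.0224, and 0.0272 with the replicate block as well, over its alternatives 0.00496 to 0.437). Adhesion and migration genes had 9 higher and 13 lower of 25 (adjusted p = 0.385), and the median of -0.19 turned to 0.06 with library totals. The integrin gene Itga4 rose from 25.5 ± 0.535 to 125 ± 4.01 CPM, and the chemokine receptor gene Ccr1 fell from 23.9 ± 0.443 to 0.075 ± 0.106 CPM, a ratio of 313 with an exact 95% counting interval of 107 to 1523. Glucocorticoid receptor targets had 7 higher and 7 lower of 16 (adjusted p = 0.651). Their median was 0.11 while the set test pointed down, and it was -0.16 with the length and GC trend removed. Lipocalin 2, Lcn2, fell from 1781 ± 231 to 200.3 ± 6.1 CPM. Of 3 AhR targets tested, 1 was higher and 1 lower: Tiparp fell from 125 ± 7.0 to 35.7 ± 1.38 CPM, and Ugt1a6a was called higher (log2 fold change 0.75, adjusted p = 0.0416), a call lost under 7 of 17 alternatives without a fold limit (adjusted p 6.7e-04 to 0.248). Ugt1a6a shares reads with its neighbouring copies and is uncertain.

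Several of the largest falls ended at 0 counts in both Rb1 libraries. Efcab6 fell from 17.8 ± 2.19 CPM (at least 117-fold lower), Ghrh, the growth hormone releasing hormone gene, from 10.8 ± 0.163 (at least 71.1-fold), Lman1l from 5.79 ± 0.954 (at least 38-fold), F7, coagulation factor VII, from 5.31 ± 0.82 (at least 34.8-fold) and Hsd17b2 from 3.4 ± 0.521 (at least 22.3-fold). Placental growth factor, Pgf, fell from 104 ± 10.7 to 0.154 ± 0.147 CPM, a ratio of 684 that is rough, since the Rb1 libraries held 1 and 5 counts. Galectin gene Lgals2 fell from 14.6 ± 0.74 to 0.0258 ± 0.0365 CPM, with 1 count in the Rb1 libraries and a ratio of 574 (95% counting interval 102 to 22701). Apart from Kif14, the 10 largest rises were of genes under 1 CPM with vehicle. Cd27, a TNF receptor family gene, rose from 0.0597 ± 2.6e-04 to 2.97 ± 0.247 CPM, a ratio of 49.8 (95% counting interval 13.5 to 416). Acsm3 rose from 0.0896 ± 0.0426 to 2.2 ± 0.632 CPM, a ratio of 24.7 (interval 8.17 to 122). Bglap3 rose from 0.448 ± 0.0442 to 12 ± 0.0186 CPM, Dbndd1 from 0.119 ± 5.3e-04 to 3.05 ± 0.428 CPM, the neuropilin gene Nrp1 from 0.149 ± 0.0415 to 2.22 ± 0.66 CPM and the kinesin gene Kif14 from 3.13 ± 0.45 to 39.1 ± 1.38 CPM. The immunoglobulin joining segment Ighj4 had 0 counts with vehicle and 2.46 ± 0.339 CPM with Rb1, at least 13.7-fold higher; the segment is 54 bases long, and its level is uncertain. Far1os, an antisense gene, rose from 0.0299 ± 0.0423 to 1.78 ± 0.0317 CPM, but strand use in counting is not given in the sources used here, so its reads cannot be told from those of the gene it overlaps.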

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

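The counts of changed genes stayed within 1.5 times the reported ones under every alternative except an added limit of 1 on the absolute log2 fold change, which by construction left 1921 genes higher and 2196 lower. Apart from that limit, genes higher ranged from 4186 to 6128 and genes lower from 3662 to 5251. Leaving out each library in turn gave 4186 to 5132 higher and 4207 to 5104 lower, with a lone library assumed to vary like the other group. DESeq2 called 4303 higher and 4405 lower. With the replicate block, 4799 were higher and 4854 lower, and 206 of the 9731 calls were lost. The block changed no list call and no call of a named gene. Camera called 5 lists higher and 18 lower. With an estimated correlation it called 0 higher and 0 lower, and fry called 8 higher and 26 lower. A correlation above the preset 0.01 does not account for every loss. For interferon-stimulated genes the estimate was -0.021, yet the unadjusted camera p went from 3.6e-14 to 0.0127. The estimates for hypoxia targets (-0.029), glycolysis (-0.046) and inflammatory genes (-0.022) were also lower. Those for cytosolic ribosomal proteins (0.90) and chemokines (0.49) were higher. These forms of camera also differ in degrees of freedom: 2 with the estimate, and near the number of genes tested with the preset. Fewer degrees of freedom raise p by themselves, so the loss of calls need not come from correlation between genes. The share of each was not tested. With the length and GC trend removed, chosen after seeing the data, 6 lists were higher and 16 lower, and with the block as well 6 and 15. The limit on the fold change ends by construction the call of 11 named genes. Apart from it, 166 of 171 named genes kept their call and direction in every alternative in which they were tested, and no named gene reversed. The exceptions lost their call in 1 of 14 alternatives (Ajm1) or in 1 to 9 of 17 (Mtf1, Cd86, Ugt1a6a and Acta2). Most named genes were picked for a small p or a large change in these same libraries, which favours keeping their call. Of all 9731 calls, 1247 were lost with library totals, 1030 with DESeq2 and 1697 with limma-trend on log2(FPKM + 1) without its filter. Leaving out a library lost calls too. With the length and GC trend removed 1736 were lost and 292 reversed, and with the block as well 1885 and 264. Depth limits low genes most: 3 counts per library correspond to 0.150 to 0.180 CPM, and with 2 libraries per group a spread between cultures is known only roughly.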

Other observations

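The 12 gene families below were chosen by symbol after their values were seen, and all tests first given in this part were chosen after the results were seen. They hold every tested gene whose symbol starts alike, pseudogenes left out, and so also relatives by name only such as Kif1bp, Usp6nl, Psmc3ip and Il18bp and noncoding genes such as Cep83os and Il1bos. The camera p-values of the families are adjusted over these 12 only. Some members, such as Kif11 and Il1b, also stand in the lists above. Passing therefore gives no separate support. Kif genes, most of them kinesins, the motors of the spindle and of axonal transport, were higher in 24 and lower in 2 of 31 cases (median log2 fold change 1.23, camera adjusted p = 1.2e-05, and adjusted p = 0.302 with an estimated correlation). Cep genes, named for centrosomal proteins, were higher in 28 of 33 and lower in 0 (median 0.91, camera adjusted p = 3.4e-06, and adjusted p = 0.302 with an estimated correlation). Nucleoporin genes were higher in 17 of 19 (median 0.94, camera adjusted p = 1.2e-04, and adjusted p = 0.336 with an estimated correlation), and Fanconi anaemia genes of DNA crosslink repair in 8 of 10 (median 1.19, camera adjusted p = 0.0115, and adjusted p = 0.458 with an estimated correlation). Usp genes, most of them ubiquitin-specific proteases, were higher in 33 of 43 (camera adjusted p = 1.2e-05, and adjusted p = 0.321 with an estimated correlation) and Integrator subunit genes in 13 of 15 (camera adjusted p = 0.00155, and adjusted p = 0.302 with an estimated correlation). All 6 families still passed with the length and GC trend removed, with smaller medians: 0.82 for Kif, 0.55 for Cep with 25 higher and 3 lower, 0.79 for nucleoporins, 0.86 for Fanconi anaemia genes, 0.28 for Usp against 0.61 before, with 25 higher and 8 lower, and 0.38 for Integrator subunits against 0.62 before, with 9 higher (adjusted p = 0.0421).

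Lower with Rb1 were genes with an Il symbol, most of them interleukins or their receptors, 27 of 39 with 4 higher (median -1.58, camera adjusted p = 2.1e-04, and adjusted p = 0.302 with an estimated correlation), and Atp6 genes, subunits of the vacuolar proton pump and accessory proteins, 13 of 19 with 2 higher (median -0.84, camera adjusted p = 0.00427, and adjusted p = 0.321 with an estimated correlation). Psma to Psmd genes, most of them proteasome subunits, were lower in 31 of 39 with 4 higher (median -0.50, camera adjusted p = 3.3e-04, and adjusted p = 0.463 with an estimated correlation) and mitochondrial ribosomal proteins in 48 of 77 with 3 higher (median -0.41, camera adjusted p = 1.6e-04, and adjusted p = 0.526 with an estimated correlation). With the length and GC trend removed, the proteasome family had a median of -0.22 with 25 lower and 4 higher (adjusted p = 0.0191), and the mitochondrial ribosomal proteins did not pass (median -0.19, 39 lower and 17 higher, adjusted p = 0.0562). With library totals these medians were -0.24 and -0.16. Schlafen genes had 5 lower and 2 higher of 7 and did not pass (adjusted p = 0.0709), nor did 310 Zfp genes, named for zinc finger proteins, of which 107 were higher and 59 lower (median 0.09, adjusted p = 0.291). All 12 family medians kept their sign with library totals and with relative log expression factors. With the length and GC trend removed the zinc finger median turned to -0.02, with 72 higher and 82 lower (adjusted p = 0.975), and the other 11 kept their sign. Over protein-coding genes of at least 5 CPM, the median log2 fold change of the 19 autosomes lay between -0.06 on chromosome 7 and 0.20 on chromosome 3, and that of the X chromosome was 0.25. The chromosome medians are not corrected for gene length. Medians of the same genes ran from -0.66 to 0.77 over the length classes, so no effect of a chromosome is read from them.

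Inflammatory, interferon, hypoxia and glycolysis genes were lower and mitosis genes higher in the same libraries. The values argue against a gene length and GC trend as the whole cause: with it removed, the 6 list medians stayed on their side, and the nearest to 0 was 1.26 away, that of glycolysis. A different state of the cultures, in density, oxygen supply or stimulation, was not tested: that 19 of 20 hypoxia targets fell is part of the pattern and supports no explanation of it. Each group was its own cultures and the labels give no density or passage, so such a state and the compound cannot be told apart, and an action of Rb1 itself stays open as untested.

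Over 9656 protein-coding genes, the log2 fold change rose by 1.53 per 10-fold of gene length (Spearman's rho 0.473 across genes), from a median of -0.66 in the shortest of 10 length classes to 0.77 in the longest. The vehicle replicates, with no treatment between them, also differed along length, with a slope of -0.31 for replicate 1 minus replicate 2, which is -0.205 times the slope between groups, and a Spearman's rho of -0.461 across genes, about as far from 0 as that between groups. The slope between the Rb1 replicates was 0.05 (rho 0.120). A length-dependent difference in RNA integrity or library preparation may therefore contribute. Whether it accounts for the trend between groups cannot be told apart from an effect of Rb1 with these libraries.

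The mRNAs of the mitochondrial genome were higher while 24 of 35 nuclear oxidative phosphorylation genes were lower and 2 higher, a difference that shrank to 17 and 7 with library totals and to 16 and 8 with the length and GC trend removed, where that list did not pass (adjusted p = 0.366). The median of the mitochondrial mRNAs rose to 2.50 with the length and GC trend removed, which argues against that trend as the cause, and a single abundant gene does not account for the rise, since each of the 12 mRNAs was called higher (the other 11 without mt-Co1 had a median of 1.89). A general rise of all mitochondrial RNA would raise the rRNA counts too, if all libraries captured rRNA alike. Yet mt-Rnr1 had a log2 fold change of -1.29 (SE 0.12) and mt-Rnr2 of 0.14 (SE 0.15). Mitochondrial rRNA held only 0.165% ± 0.0321 of the counts with vehicle and 0.115% ± 7.8e-04 with Rb1. An earlier bound, that both rRNAs fall by more than 2 standard errors, was not met by mt-Rnr2, and the bound used instead, a rise of less than 1 for both, was set after that was seen. Of 10 mitochondrial tRNAs tested, 6 were higher, all at or under 0.657 CPM with vehicle, and 1 was lower. The 3 of at least 10 CPM with vehicle were not higher: mt-Tp had a log2 fold change of -0.70 (SE 0.10), mt-Tn of -0.31 (SE 0.16) and mt-Tc of -0.14 (SE 0.20). As counted, not every mitochondrial RNA rose alike, while a rise of the mRNAs with part of the tRNAs is not excluded. How the libraries captured RNA is not given in the sources used here. Counts in these rRNA and tRNA genes therefore need not measure rRNA and tRNA levels, and a general rise cannot be excluded from them. A difference in how the libraries captured mitochondrial mRNA, and an effect of Rb1 on it, stay open and were not tested.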
